A study of Mus musculus with 24 samples.

How the data were processed

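Bulk RNA sequencing was done on lumbar spinal cord of 24 adult C57BL/6J mice, per the labels' protocols. The labels place 3 mice in each of 8 groups, which cross genotype (wild-type or a conditional knockout of Chrna7 restricted to myeloid cells), treatment (vehicle or paclitaxel) and sex. Paclitaxel, a taxane that stabilises microtubules, was given at 1 mg per kg in 4 injections, and RNA was taken on day 7 after the first injection, per the labels' protocols. Each library comes from a separate mouse, so the spread between replicates holds both the animal and the library. The replicate numbers of the labels run from 1 to 3 in each group, and nothing in the labels says that they pair animals.

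The values are whole-number counts per gene symbol, deposited by the authors as 1 table without normalization. Reads were aligned with STAR, whose version is not given in the sources used here, and counted with featureCounts 1.6.2, per the submitters' processing notes. The counting used the exons of the Ensembl GRCm38 annotation release 96, summed by gene name and without strand, per the file headers. The counting command held no option for read pairs, per the file headers. Genes with 1 to 20 counts had an odd count in 34.4 to 37.3% of cases, fewer than chance gives, as separate counting of both mates would leave. Both mates of a pair were taken as counted as separate reads, which roughly doubles the totals without adding molecules. Reads that map to several places or overlap several genes were not counted, so near-identical genes, overlapping genes and antisense partners cannot be told apart. The table held 55418 genes, and its 37 mitochondrial genes were at 0 in every library, so the mitochondrial share could not be used as a sign of RNA quality.

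The total was 88812295 to 112158154 counts per library (median 94343662), and 22024 to 23269 genes had 10 or more counts. No 2 replicates of a group agreed within sampling noise. The lowest chi-square per degree of freedom of a replicate pair was 8.99, so no library was counted as deposited a second time within its group. Libraries of different groups were not compared in this way.

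Counts were fitted with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr over the 8 groups, libraries were scaled by TMM factors, and quasi-likelihood models with robust dispersions were fitted to the means of the 8 groups. Means of groups are given in CPM with TMM factors, as mean ± SD over the libraries of a group where a spread is given. Values of single libraries, ranges over libraries, the sum of Lyz1 and Lyz2, shares and ratios made from CPM, the values of lists per library and the figures rest on CPM from the library totals alone, without TMM factors. Adjusted p values called edgeR adjusted p are Benjamini-Hochberg values of the edgeR quasi-likelihood test over all tested genes, and a gene was called when that value lay under 0.05. Log2 fold changes carry the standard error (SE) of the fit. The 15 contrasts were fixed with the other choices before the data were examined: paclitaxel against vehicle within each genotype and over all animals, knockout against wild-type under each treatment and over all animals, males against females, the 3 interactions of 2 factors, the interaction of all 3 factors, and paclitaxel against vehicle within each of the 4 combinations of genotype and sex. The interaction of sex and treatment is the paclitaxel response of males minus that of females. The interaction of genotype and treatment is the response of knockout minus that of wild-type, and the interaction of sex and genotype is the knockout effect in males minus that in females. Unless stated otherwise, these signs apply to genes and to lists.

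Lists of cell type markers, pathways and gene families, 44 in all, were also fixed in advance, and 43 had the minimum of 5 tested genes. They were tested with camera (limma 3.58.1) at the preset correlation of 0.01 between genes, and adjusted over the lists of a contrast. This value is called camera adjusted p. Camera with a correlation estimated from the data, and fry, were run beside it. Members of a list were also tested with their edgeR p adjusted over the list alone. Genes are named by a rule fixed in advance. For the first 8 contrasts it takes the 10 genes with the largest rise and the 10 with the largest fall among those called with a mean of at least 1 CPM, or the 10 smallest p where fewer than 5 passed, given as values. For the other contrasts it takes the 5 smallest p. In each contrast it adds up to 4 members of each list that pass over all genes or over their list alone, and 7 genes named in advance (Chrna7, Lyz2, Cx3cr1, Gfap, Aif1, Il1b and Tnf). Only part of the genes that the rule allows are printed.

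All 24 libraries enter the fit fixed in advance. The library of wild-type female paclitaxel replicate 3 had the profile of another tissue, and every test was therefore repeated on the 23 other libraries, a choice made after seeing the data. The 24 libraries gave 24725 tested genes and a common biological coefficient of variation of 0.231. The 23 libraries gave 25372 tested genes and a coefficient of 0.103. The filter keeps more genes in the smaller set because a group of 2 libraries lowers the number of libraries a gene must be found in. Values are given for the 24 libraries first and for the 23 libraries beside them.

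The procedure was tested on simulated counts drawn from the mean of each gene, the totals of the real libraries and the dispersions of the 23-library fit. Changes were put only into genes with a mean of at least 1 CPM. In the set of 24 libraries, wild-type female paclitaxel replicate 3 was drawn from its own profile. For paclitaxel against vehicle in wild-type, that set (24428 genes) recovered 44.8% of the genes changed 1.5-fold and 53% of those changed 2-fold. The set of 23 libraries (24764 genes) recovered 76.1% and 100%. Of the genes changed 1.25-fold, 26.9% were recovered in the set of 24 libraries and 59.7% in that of 23, so smaller changes are often missed on both. The alternatives tried were DESeq2 1.42.0 size factors, no filter on low counts, only genes with a mean of at least 1 CPM, the DESeq2 Wald test, limma voom, the replicate number as a block, 1 surrogate variable (sva 3.50.0), each library left out in turn, and, for 4 contrasts, a fit of the 12 libraries compared. Correlations of responses were computed across genes between contrasts that share no library, beside 100 draws of permuted treatment labels. Positions of genes are those of GRCm38, 1-based.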

Results

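RNA was measured in lumbar spinal cord of 24 mice, 3 in each of 8 groups formed by genotype, treatment and sex. The design asks 3 things: what paclitaxel, a cancer drug that causes painful neuropathy, does to the cord, what the loss of Chrna7 from myeloid cells does, and whether the loss changes the response to the drug. Chrna7 encodes the alpha7 subunit of the nicotinic acetylcholine receptor. Libraries held 88812295 to 112158154 counts, and all 12 males and 12 females showed the sex chromosome transcripts of their label. Ddx3y, from the Y chromosome, lay at 118 to 163 CPM in males and at most 1.28 CPM in females.

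One library had the profile of a sensory ganglion. In wild-type female paclitaxel replicate 3, all 14 genes of the list of dorsal root ganglion neurons lay above the median of the other 23 libraries, with a median log2 ratio of 8.52. Scn10a, a sodium channel of nociceptors, reached 772 CPM (without TMM factors, as are the other levels of this library) against at most 0.728 CPM in any other library, and Mrgprd, a receptor of nonpeptidergic nociceptors, reached 139 CPM against at most 0.0832 CPM. Calca, the gene of CGRP, lay at 1546 CPM (24.5 to 62.7 CPM in the others). The skeletal muscle list was also higher, in 11 of 11 members. Lists of cord glia and of inhibitory neurons were low. The astrocyte list lay at 7.88% of the median of the others, the list of oligodendrocytes and myelin at 10.3%, inhibitory neurons at 8.51% and microglia at 19.3%. Of the lists of other cord neurons, that of motor neurons lay at 103% (6 of 12 members higher), with log2 ratios of -5.40 to 5.48. It shares Calca with the ganglion list, so its median does not show that motor neurons were present. The list of dorsal horn excitatory neurons lay at 80.6% (5 of 12 higher), with log2 ratios of -4.77 to 3.81. Gfap, the astrocyte filament, lay at 42.5 CPM against 1015 to 1626 CPM. The comparisons that contain wild-type females given paclitaxel are therefore given with and without this library.

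**Figure D1:**
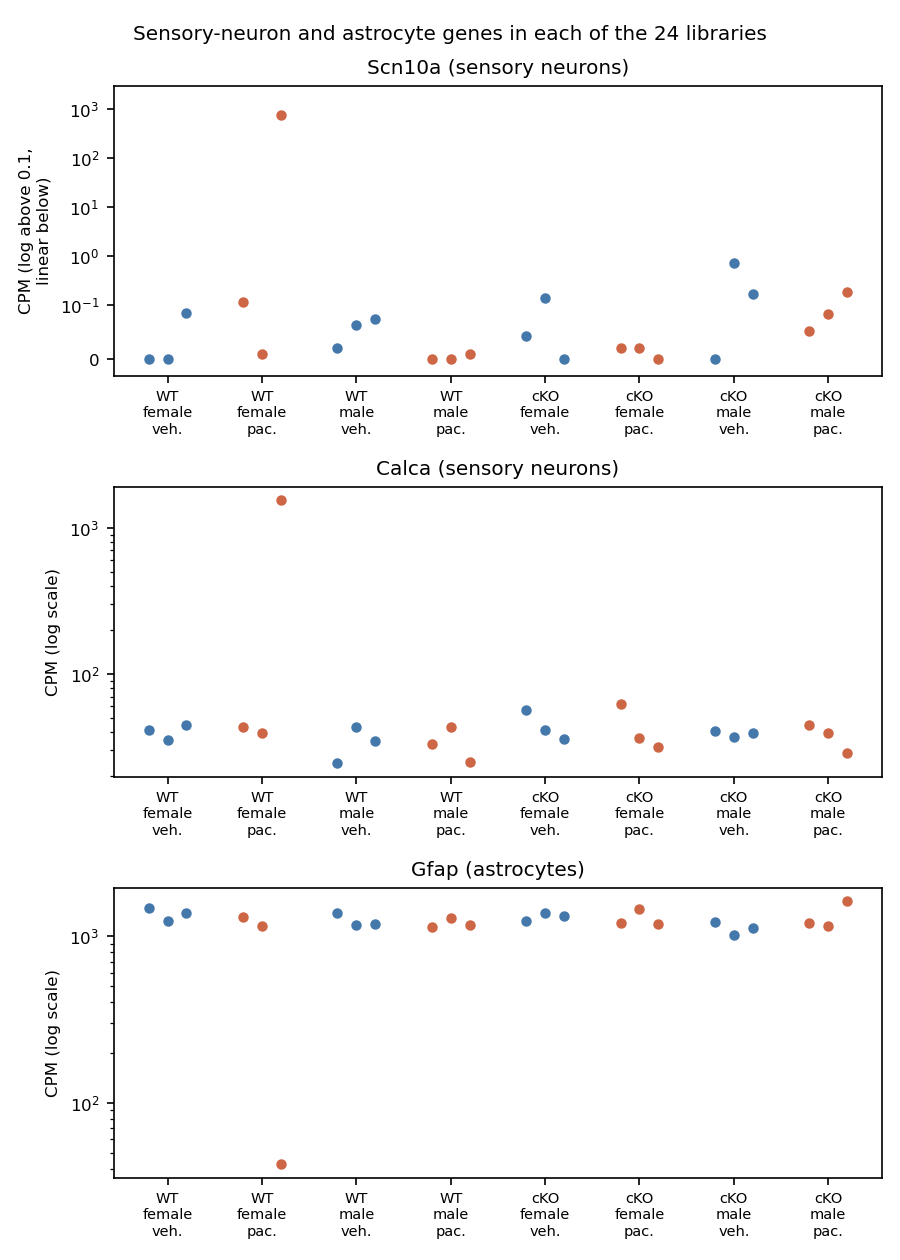
Levels of Scn10a, Calca and Gfap in CPM on log axes (linear below 0.1 CPM for Scn10a), 1 point per library, by genotype, sex and treatment (blue vehicle, red paclitaxel; WT wild-type, cKO knockout). Replicate 3 of wild-type females given paclitaxel lies far above the other 23 libraries for Scn10a (772 CPM) and Calca (1546 CPM) and far below them for Gfap (42.5 CPM).

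The targeted gene, Chrna7 (chromosome 7, 63098692 to 63212569), was not called in any of the 15 contrasts by edgeR. Its level, without TMM factors, was 9.09 to 15.9 CPM in 23 libraries and 48.1 CPM in wild-type female paclitaxel replicate 3. Knockout against wild-type over all animals gave a log2 fold change of -0.33 over 24 libraries and -0.11 (SE 0.06) over 23 libraries, where knockout cords held 12.6 ± 1.61 CPM (SD, n = 12) and wild-type cords 13.6 ± 1.79 CPM (n = 11). The smallest edgeR adjusted p of this gene was 0.125 over 24 and 0.257 over 23 libraries. The gene is also transcribed by neurons, so whole cord counts cannot show a loss from myeloid cells, and this check neither bears out nor contradicts the labels. Of the other genes named in advance, Gfap, Aif1, Il1b and Tnf were called in 0 of the 15 contrasts on either set of libraries, with smallest edgeR adjusted p of 0.295, 0.576, 0.223 and 0.421. Il1b and Tnf lay near the floor, with medians of 0.271 and 0.1335 CPM over 24 libraries without TMM factors, so changes in them could go unseen. Cx3cr1 was called in 2 contrasts, both over 23 libraries, and Lyz2 in 1.

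Knockout cords differed from wild-type cords in a pair of lysozyme genes. Lyz2, which encodes the lysozyme of macrophages and neutrophils, lay at 18.95 ± 4.73 CPM in knockout and 40.4 ± 9.91 CPM in wild-type (n = 12 each). It fell by 1.11 on the log2 scale (SE 0.13, edgeR adjusted p = 0.00149), and all 12 knockout cords lay below the wild-type mean. Its neighbour Lyz1, the lysozyme of Paneth cells in the intestine, rose from 0.489 ± 0.308 to 1.56 ± 0.405 CPM, a log2 fold change of 1.73 (SE 0.22, edgeR adjusted p = 0.00351). These were the only 2 genes of 24725 called over all animals, with 884 at an unadjusted p under 0.05, 2 by the DESeq2 Wald test and 2 by limma voom. Over 23 libraries Lyz2 fell by 1.06 (SE 0.13, edgeR adjusted p = 0.00752) and Lyz1 rose by 1.92 (SE 0.18, edgeR adjusted p = 1.49e-06). The genes lie 10466 bases apart on chromosome 10 (Lyz2 at 117277331 to 117282321, Lyz1 at 117287797 to 117292868) and are near-identical in sequence, so the counts of each are uncertain. Without TMM factors, Lyz1 and Lyz2 together held 20.6 ± 4.98 CPM in knockout and 40.8 ± 10.0 CPM in wild-type.

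**Figure D2:**
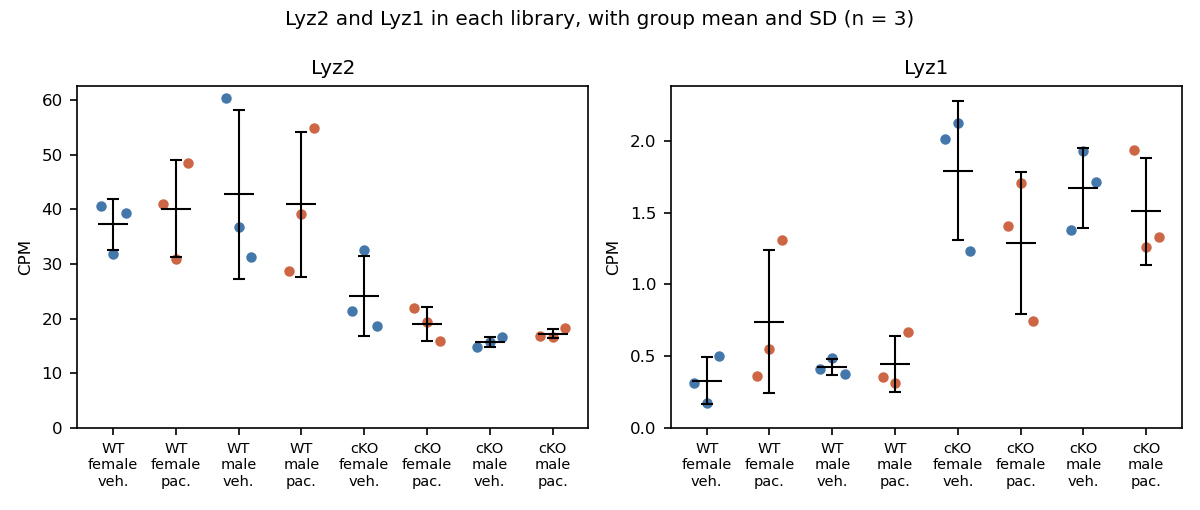
Lyz2 and Lyz1 in each library, in CPM, with the mean and SD of each group of 3 (blue vehicle, red paclitaxel; WT wild-type, cKO knockout). Lyz2 spans 14.9 to 32.5 CPM in knockout and 28.7 to 60.3 CPM in wild-type cords, and the order is reversed for Lyz1.

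The macrophage and interferon lists moved down with Lyz2 in knockout cords, though only with the preset correlation. Of the 14 genes of border macrophages and monocytes, 11 had a negative log2 fold change over 24 libraries (camera adjusted p = 1.23e-05, adjusted p = 0.573 with an estimated correlation), and 10 over 23 libraries (camera adjusted p = 6.05e-04, adjusted p = 0.542 with an estimated correlation). The other 13 members had a median of -0.08 over 23 libraries, far less than Lyz2. All 22 genes of the interferon response were lower over 24 libraries (camera adjusted p = 2.36e-07, adjusted p = 0.573 with an estimated correlation). Over 23 libraries 21 of the 22 were lower (camera adjusted p = 6.05e-04, adjusted p = 0.840 with an estimated correlation), but without wild-type male vehicle replicate 1 the direction was reversed and the adjusted p was 0.9996. Of the dorsal horn excitatory neuron list, 11 of 12 members were lower over 23 libraries (camera adjusted p = 6.05e-04, adjusted p = 0.384 with an estimated correlation). Among them Prrxl1, a transcription factor of the nociceptive circuit, had a log2 fold change of -0.16 and passed adjusted over the list alone. The only list that held with an estimated correlation was that of the sex chromosome genes over 23 libraries, with 5 of 10 higher (adjusted p = 0.0456 with an estimated correlation, fry 0.161). Over 23 libraries Ddx3y was called as well, with 5 genes called in all without wild-type female paclitaxel replicate 1. It had a log2 fold change of 2.08 (edgeR adjusted p = 1.78e-04) that rests on female libraries near 0, with 4 to 22 counts in knockout and 0 to 6 counts in wild-type females.

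Within each treatment Lyz2 was not called, and Lyz1 was called under vehicle on both sets of libraries and under paclitaxel only over 23. Under vehicle, Lyz1 rose by 2.20 on the log2 scale, from 0.377 ± 0.121 to 1.73 ± 0.359 CPM (n = 6 each, edgeR adjusted p = 0.0408). It was the only gene called over 24 libraries, with 500 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma voom. Lyz2 lay at 19.8 ± 6.52 against 40.1 ± 10.5 CPM (log2 fold change -1.05, edgeR adjusted p = 0.189). The call of Lyz1 was lost without any 1 of 17 of the 24 libraries, with an edgeR adjusted p of up to 0.254, but over 23 libraries it was 5.04e-05. Under paclitaxel, edgeR called 0 genes over 24 libraries, with 2391 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma voom. Lyz2 there lay at 18.1 ± 2.21 against 40.8 ± 10.3 CPM (edgeR adjusted p = 0.0905), which passed without wild-type male paclitaxel replicate 1 (0.0328), wild-type male vehicle replicate 1 (0.0192) or knockout female vehicle replicate 2 (0.0459). Over 23 libraries only Lyz1 was called under paclitaxel, at 1.40 ± 0.410 CPM (n = 6) against 0.446 ± 0.147 CPM (n = 5), with a log2 fold change of 1.63 (edgeR adjusted p = 0.0291). That call was lost without any 1 of 13 further libraries, with an adjusted p of up to 0.352. It was also lost with limma voom, with the replicate block and with 1 surrogate variable.

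Under vehicle, several other lists differed between the genotypes by camera over 23 libraries, and none of them held with an estimated correlation. Microglial markers were lower in 19 of 20 (camera adjusted p = 2.70e-07, adjusted p = 0.408 with an estimated correlation), with Cx3cr1, the fractalkine receptor, at 37.1 ± 3.90 against 41.0 ± 3.18 CPM (edgeR adjusted p = 0.911). Cell cycle genes were lower in 16 of 20 (camera adjusted p = 3.53e-06, adjusted p = 0.316 with an estimated correlation), and 5 of them passed adjusted over the list alone. One was the mitotic kinase gene Bub1, at 0.147 ± 0.0863 against 0.276 ± 0.115 CPM, which is near the floor.

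Paclitaxel left no called gene in wild-type cords. Over 24 libraries edgeR called 0 genes, with 2673 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma voom, and over 23 libraries 0 genes, with 2021 at an unadjusted p under 0.05, 4 by DESeq2 and 0 by limma voom. Genes with small p over 23 libraries were Jcad, an endothelial junction gene, at 68.0 ± 4.56 CPM with paclitaxel (n = 5) and 80.8 ± 6.66 CPM with vehicle (n = 6), and Vstm4, at 25 ± 2.27 against 19.3 ± 1.35 CPM. Both had an edgeR adjusted p of 0.129, and both passed, as did Crybg3, only without wild-type male paclitaxel replicate 1 (0.0455), which gave 4 called genes. Gpr17, a receptor of differentiating oligodendrocyte precursors, lay at 20.4 against 27.4 CPM and passed adjusted over the list alone. All 10 genes of oligodendrocyte precursors were lower (camera adjusted p = 2.18e-05, adjusted p = 0.206 with an estimated correlation), as were 19 of 20 microglial genes (camera adjusted p = 1.34e-05, adjusted p = 0.905 with an estimated correlation). The ribosomal protein list was higher in 81 of 86 genes (camera adjusted p = 1.30e-12, adjusted p = 0.987 with an estimated correlation). With the ganglion-like library included, the list of dorsal root ganglion neurons was higher in 13 of 13 tested genes, with a median log2 fold change of 3.49 (adjusted p = 0.680 with an estimated correlation).

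In knockout cords, paclitaxel went with lower clock genes and with higher Vstm4. With 24 libraries edgeR called 0 genes, with 1065 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma voom. Over 23 libraries it called 6, with 183 by DESeq2, 6 by limma voom and 1 in a fit of the 12 knockout libraries alone. The library that was left out is not in this comparison and acted on it through the estimate of the spread, the genes tested and the scaling. Nr1d2, a nuclear receptor of the circadian clock (REV-ERB beta), fell from 229 ± 10.8 to 191 ± 10.3 CPM (n = 6 each), a log2 fold change of -0.26 (SE 0.04, edgeR adjusted p = 0.00863). Klf9, a glucocorticoid-induced transcription factor, fell from 161 ± 12.6 to 135 ± 8.30 CPM (edgeR adjusted p = 0.0129), and Usp53, a tight junction gene, from 78.4 ± 6.74 to 64.9 ± 4.92 CPM (edgeR adjusted p = 0.0129). Gli1, the transcription factor and target of Hedgehog signalling, fell from 14.1 ± 1.75 to 10.6 ± 0.816 CPM (edgeR adjusted p = 0.0420). Vstm4 rose from 20.1 ± 1.62 to 26.5 ± 2.16 CPM (log2 fold change 0.40, edgeR adjusted p = 0.0108), and Fah, an enzyme of tyrosine breakdown, from 43.2 ± 0.857 to 50.1 ± 2.29 CPM (edgeR adjusted p = 0.0129). Each of the 6 had the same direction in 6 of 6 cords. None of the 6 passed without knockout male vehicle replicate 2 (Nr1d2 0.0686, Vstm4 0.0816), and the count was 332 without knockout male vehicle replicate 1, 1 without knockout female vehicle replicate 3, and 3 without knockout female vehicle replicate 1, female paclitaxel replicate 1 or 2, or male paclitaxel replicate 3.

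The clock list was the only one to hold with an estimated correlation in knockout cords. Over 23 libraries 12 of its 15 genes were lower and 3 higher with paclitaxel (camera adjusted p = 1.47e-08, adjusted p = 0.00948 with an estimated correlation, fry 0.00133), and 12 passed adjusted over the list alone. Per2, a repressor of the clock, lay at 26.3 against 33.8 CPM, and Arntl, its activator (BMAL1), at 18.9 against 15.5 CPM. Over 24 libraries the list also passed (camera adjusted p = 4.71e-05, adjusted p = 0.478 with an estimated correlation). Endothelial genes were higher in 11 of 12 over 23 libraries (camera adjusted p = 7.53e-11, adjusted p = 0.225 with an estimated correlation), and 7 passed adjusted over the list alone. Cldn5, the tight junction claudin of brain vessels, lay at 37.5 ± 3.53 against 24.6 ± 6.59 CPM, and Kdr, the VEGF receptor, at 18.7 against 11.2 CPM. Tubulins and microtubule proteins, the targets of the drug, were higher in 19 of 24 (camera adjusted p = 7.17e-09, adjusted p = 0.368 with an estimated correlation), with 12 adjusted over the list alone. Tuba1b lay at 290 against 253 CPM and Tubb4b at 318 against 276 CPM. Over all genes, Cldn5, Tuba1b, Tubb4b and Per2 were not called, but each passed without knockout male vehicle replicate 1 (edgeR adjusted p = 0.0117, 0.0209, 0.0167 and 0.0297), and Arntl without that library (0.0301) or knockout female paclitaxel replicate 3 (0.0316).

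Over both genotypes together, paclitaxel went with a shift of clock genes in both directions. With 24 libraries edgeR called 0 genes, with 1848 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma voom. Over 23 libraries it called 5 genes, with 242 by DESeq2 and 5 by limma voom. Of the 5, DESeq2 called 3 and limma voom 4. Vstm4 rose from 19.7 ± 1.49 (n = 12) to 25.8 ± 2.24 CPM (n = 11), a log2 fold change of 0.38 (SE 0.05, edgeR adjusted p = 1.63e-04), in 11 of 11 cords. Inmt, an indolethylamine methyltransferase gene, fell from 1.68 ± 0.308 to 0.900 ± 0.313 CPM (log2 fold change -0.94, edgeR adjusted p = 0.00676), and Usp53 from 77.6 ± 5.22 to 66.1 ± 5.62 CPM (edgeR adjusted p = 0.00654). The clock repressors Ciart and Nr1d2 fell by 0.28 and 0.16 on the log2 scale (edgeR adjusted p = 0.0347 for both). The call of Inmt was lost without wild-type female paclitaxel replicate 1 (0.0525), that of Ciart without any 1 of 12 libraries and that of Nr1d2 without any 1 of 17. The count of genes was 2 without wild-type female paclitaxel replicate 1, 62 without knockout male vehicle replicate 1, 19 without wild-type male paclitaxel replicate 1, and 3 to 6 without any other.

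Of the 15 clock genes, 12 were lower and 3 higher with paclitaxel over 23 libraries (camera adjusted p = 3.71e-09, adjusted p = 0.00546 with an estimated correlation, fry 0.00101), and 11 passed adjusted over the list alone. Arntl had a log2 fold change of 0.20 and its partner Npas2 of 0.22, while Per2 had -0.26, Per3 -0.23 and Dbp -0.38. Over all genes, Per2 was called only without knockout male vehicle replicate 1 (0.0467) or wild-type female paclitaxel replicate 2 (0.0387), and Arntl only without wild-type male paclitaxel replicate 1 (0.0414). The list had a negative median in females (-0.15, 12 of 15 lower) and in males (-0.08, 10 of 15 lower). Over 24 libraries it passed with the preset correlation (camera adjusted p = 2.14e-08, adjusted p = 0.692 with an estimated correlation), but the ganglion-like library, a paclitaxel library, had 14 of the 15 genes below the other libraries, with a median log2 ratio of -1.13, which adds to this value in the same direction. In wild-type cords alone, 12 of the 15 were lower over 23 libraries without holding (camera adjusted p = 0.00604, adjusted p = 0.440 with an estimated correlation). The interaction of genotype and treatment did not pass for this list over 23 libraries (camera adjusted p = 0.0768), so its response is not shown to differ between the genotypes. Neutrophil genes were higher in 12 of 13 with a median log2 fold change of 1.09 (camera adjusted p = 3.30e-07, adjusted p = 0.680 with an estimated correlation), and 5 passed adjusted over the list alone. Camp, an antimicrobial peptide of neutrophil granules, lay at 1.55 ± 1.26 against 0.666 ± 0.366 CPM. A few cords carried this: the median of the list was 1.34 to 1.99 CPM in 4 of the 11 paclitaxel cords, and 0.127 to 0.811 CPM in the other 7 against 0.127 to 0.770 CPM with vehicle. The log2 fold change of Camp ran from 0.64 to 1.34 with 1 library left out, and its edgeR adjusted p was 0.736 without wild-type female paclitaxel replicate 1.

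**Figure D3:**
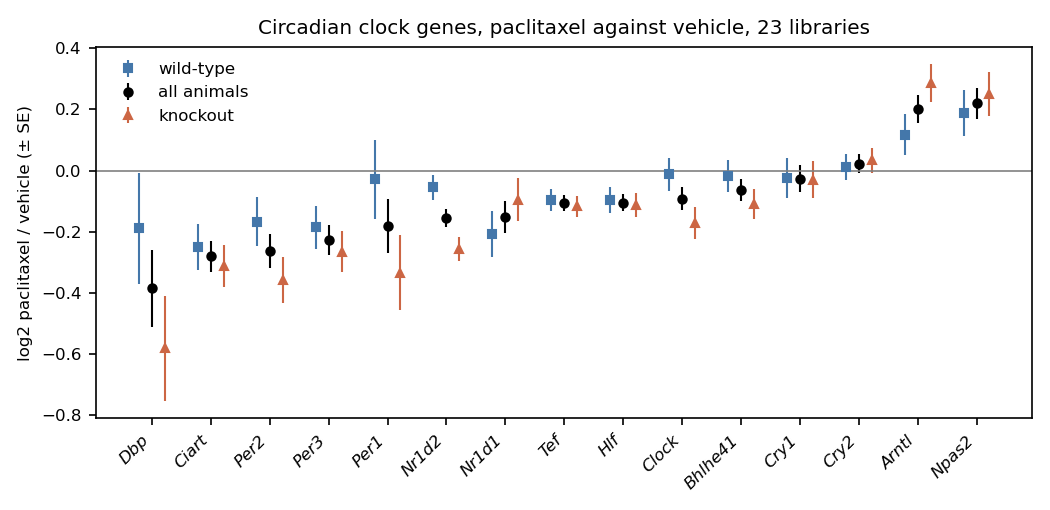
Log2 fold changes of the 15 circadian clock genes with paclitaxel against vehicle over 23 libraries, in wild-type (squares), knockout (triangles) and all animals (circles), with SE bars. Over all animals Arntl and Npas2 lie above 0, while Per2, Per3, Dbp, Ciart and Nr1d2 lie below.

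Whether the loss of Chrna7 changed the response to paclitaxel was tested by the interaction of genotype and treatment, and no gene passed, so the 6 genes called in knockout cords are not shown to respond otherwise in wild-type cords. Over 24 libraries edgeR called 0 genes, with 1389 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma voom, and the smallest adjusted p was 0.729. Over 23 libraries edgeR called 0, with 2134 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma voom, and the smallest adjusted p was 0.496. Genes with small p over 23 libraries were Actn4, a cytoskeletal alpha-actinin (log2 difference 0.28), and Msn, which encodes moesin (0.40). Among the lists over 23 libraries, tubulins and microtubule proteins had a more positive response in knockout in 22 of 24 genes (camera adjusted p = 1.48e-08, adjusted p = 0.287 with an estimated correlation). Microglial genes did so in 18 of 20 (adjusted p = 0.480 with an estimated correlation), with Csf1r, the receptor that microglia depend on, at a log2 difference of 0.33. Ribosomal protein genes had a more negative response in 77 of 86 (camera adjusted p = 2.78e-15, adjusted p = 0.510 with an estimated correlation).

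Males and females differed in genes of the sex chromosomes and in genes elsewhere. Over 24 libraries edgeR called 28 genes, 13 higher and 15 lower in males, with 101 by DESeq2 and 26 by limma voom. Over 23 libraries it called 233, of which 118 were higher and 115 lower, with 625 by DESeq2 and 219 by limma voom, and all 28 were among them. All 10 genes of the sex chromosome list were called. Ddx3y lay at 133 ± 12.2 CPM in males, and Xist, the RNA that silences 1 X chromosome, at 0.677 against 810 ± 106 CPM (n = 12 each, edgeR adjusted p = 1.83e-15). Genes that escape this silencing were lower in males, such as Eif2s3x (53.8 against 88.4 CPM), Kdm6a (log2 fold change -0.68), Kdm5c (-0.51) and Ddx3x (-0.46). The list's camera test pointed down over 24 libraries and up over 23, with medians of -0.49 and -0.48 and a positive mean, since 4 genes of the Y chromosome oppose 6 of the X. The count of 233 became 65 without wild-type female paclitaxel replicate 1 and 136 to 155 without any 1 of 6 other libraries, and over 24 libraries the count was 16 without knockout male vehicle replicate 2 and 54 without wild-type female paclitaxel replicate 2.

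A run of neighbouring genes at the far end of the X chromosome was higher in most males. Hccs, which attaches haem to cytochrome c, lay at 72.2 ± 19.3 CPM in males and 42.0 ± 2.74 CPM in females over 24 libraries (log2 fold change 0.77, edgeR adjusted p = 0.0225). Msl3, a subunit of a histone acetyltransferase complex, Prps2, a phosphoribosyl pyrophosphate synthetase gene, and BC022960 rose by 0.76, 0.73 and 0.87. The 4 calls were lost without any 1 of 16, 10, 18 and 7 of the 24 libraries, with an adjusted p of up to 0.106. Over 23 libraries Tlr7, the receptor of single-stranded RNA, was called too, at 6.67 ± 2.05 against 3.76 ± 0.445 CPM (edgeR adjusted p = 0.0257). The 9 expressed genes from Tmsb4x to BC022960 (X chromosome, 167207093 to 169370003) had a median ratio to the female mean of 1.69 to 2.08 in 9 of the 12 males and of 0.959 to 1.07 in the other 3. In 11 females it was 0.927 to 1.05.

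**Figure D4:**
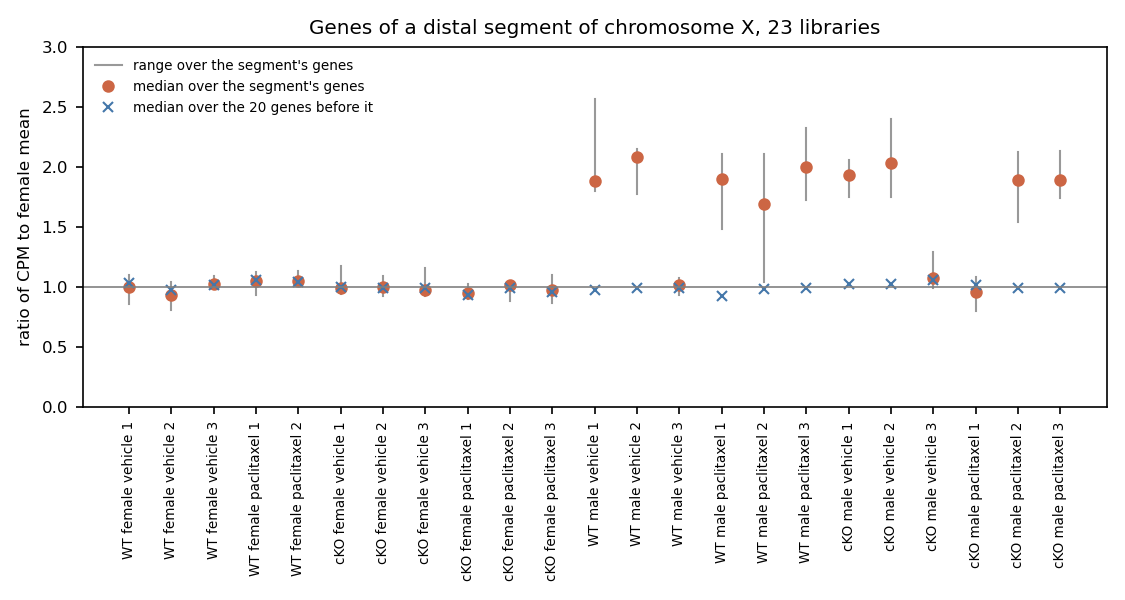
Median and range, over the 9 genes from Tmsb4x to BC022960, of the ratio of CPM to the female mean in each of 23 libraries (WT wild-type, cKO knockout), with the median of the 20 genes before them as crosses. In 9 males the median lies at 1.69 to 2.08, while the 20 genes before lie at 0.922 to 1.06 in all 23 libraries.

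Outside the sex chromosomes, the called gene with the largest male excess over 24 libraries was Srd5a2, the steroid 5-alpha-reductase that makes dihydrotestosterone. It lay at 5.74 ± 1.13 CPM in males and 1.39 ± 0.444 CPM in females (n = 12 each), a log2 fold change of 2.05 (SE 0.17, edgeR adjusted p = 5.61e-07), and 12 of 12 males lay above the female mean. Angptl1, an angiopoietin-like gene, fell to 1.01 from 1.62 CPM. Over 23 libraries, the gene of gastrin-releasing peptide, Grp, an itch transmitter of the dorsal horn, rose by 0.77 (SE 0.08), from 4.56 ± 0.751 to 7.79 ± 0.834 CPM (edgeR adjusted p = 1.67e-07). Penk, which encodes the enkephalins, rose from 92.8 ± 9.46 to 123 ± 17.9 CPM (edgeR adjusted p = 0.00158), and Prok1, a prokineticin gene, from 0.447 to 1.01 CPM. Of the microglial list, Fcrls fell from 10.9 ± 1.38 to 6.33 ± 1.87 CPM (log2 fold change -0.79, edgeR adjusted p = 0.00992) and Gpr34 from 16.6 to 13.9 CPM, while Cst7, a marker of activated microglia, rose by 0.97. The calls of Gpr34 (0.0683) and of Nts (0.129), the neurotensin gene at 17.8 against 20.2 CPM, were lost without wild-type female paclitaxel replicate 1, and that of Cst7 without any 1 of 13 libraries. Dpt, an extracellular matrix gene of meningeal fibroblasts, fell from 5.74 to 4.15 CPM, and 12 of 13 genes of that list were lower (adjusted p = 0.949 with an estimated correlation). All 18 genes of cholesterol synthesis were higher (camera adjusted p = 3.59e-05, adjusted p = 0.949 with an estimated correlation), with 9 adjusted over the list alone.

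The interaction of sex and treatment, which coincides with the numbering of the libraries, had many called genes once the ganglion-like library was left out. Over 24 libraries edgeR called 0 genes for the interaction of sex and treatment, with 3095 at an unadjusted p under 0.05, 394 by DESeq2 and 0 by limma voom, and 106 without knockout male vehicle replicate 1. Over 23 libraries it called 1259, of which 690 were more positive in males and 569 more negative, with 2520 by DESeq2 and 1132 by limma voom. Fcgrt, the neonatal Fc receptor, had the smallest p, with a difference of 0.60 (SE 0.08, edgeR adjusted p = 0.00135), followed by the kinase-like gene Coq8a (0.42, edgeR adjusted p = 0.00421) and by Efhd1 (0.43), Chst8 (0.49) and Snrpa (0.38). Tubulins had more positive responses in males in 20 of 24 genes, 7 of them called, such as Tuba1a (0.40) and Tubb4a (0.45), with an adjusted p = 0.459 for the list with an estimated correlation. All 12 endothelial genes did so (adjusted p = 0.459 with an estimated correlation), with Abcb1a, the drug efflux pump of the blood-brain barrier, at 0.67. Genes of inhibitory neurons followed in 10 of 12 (adjusted p = 0.459 with an estimated correlation), with Pax2 at 0.41 and the transporter gene Slc32a1 at 0.31. Oprm1, the mu opioid receptor gene, had a difference of -1.05 and ribosomal protein genes were more negative in 74 of 86 (adjusted p = 0.528 with an estimated correlation), such as Rpl26 at -0.30. The calls of Rpl26 (0.0686) and Abcb1a (0.0640) were lost without wild-type female paclitaxel replicate 1, those of Slc32a1 (0.0626) and again Abcb1a without replicate 2, and that of Oprm1 without any 1 of 12 libraries.

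This interaction cannot be told apart from the numbering of the libraries. Numbers 1 to 12 hold exactly the female vehicle and male paclitaxel cords, and numbers 13 to 24 the female paclitaxel and male vehicle cords. The skeletal muscle list moved with it as well, in 10 of 11 genes with a median difference of 2.69, and Acta1, the actin of skeletal muscle, had a difference of 3.31. The count was 361 with the mean of the muscle list as a covariate and 703 after trends on GC content and length were removed. It was 248 without wild-type female paclitaxel replicate 1, 2419 without knockout male vehicle replicate 1 and 1913 without wild-type female vehicle replicate 3, and it moved by over 1.5 times without 15 of the 23 libraries.

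Of the remaining interactions, that of sex and genotype had 0 genes called by edgeR over 24 libraries, with 2062 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma voom. Over 23 libraries it had 1, Ddx3y at -4.02, which rests on female libraries near 0 counts. DESeq2 called 250 and limma voom 0, and the count was 51 without knockout male vehicle replicate 1. Selenom, a selenoprotein gene, had a difference of -0.35 (edgeR adjusted p = 0.131) and passed without wild-type male paclitaxel replicate 1 (0.0140) or knockout male vehicle replicate 1 (0.0454). The interaction of all 3 factors had 0 genes over 24 libraries by edgeR, with 1032 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma voom. Over 23 libraries it had 0 as well, with 1393 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma voom. Tsc22d3, the glucocorticoid-induced leucine zipper gene, had a difference of -0.64 there (edgeR adjusted p = 0.874).

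Within single combinations of genotype and sex, 3 cords met 3. Within each sex the treatments coincide with library numbers 1 to 12 and 13 to 24, so these 4 comparisons cannot be told apart from the numbering. Knockout males were the only ones with called genes, and only over 23 libraries, though no gene of the interaction of all 3 factors passed. In these males 81 genes rose and 118 fell, with 1334 by DESeq2 and 152 by limma voom. The skeletal muscle list moved with them, with a mean log2 CPM of 1.05, 0.48 and 2.35 in the paclitaxel cords and -0.53, -0.24 and -0.17 in the vehicle cords. Usp53 fell from 83.5 ± 6.10 to 62.6 ± 4.10 CPM (n = 3 each, edgeR adjusted p = 0.00799), Esco1, a cohesin acetyltransferase gene, by 0.32, and Per2 by 0.55. Cldn5 rose from 19.5 ± 4.52 to 39.3 ± 0.904 CPM (log2 fold change 1.01, edgeR adjusted p = 0.0240), Cx3cr1 from 33.8 to 42.9 CPM (edgeR adjusted p = 0.0340) and Tuba1a by 0.36. All were lost without knockout male paclitaxel replicate 2 or 3 or knockout male vehicle replicate 2 or 3, and the count ran from 0 without knockout male paclitaxel replicate 2 to 1591 without knockout male vehicle replicate 1. Over 24 libraries edgeR called 0 genes in these males, with 1731 at an unadjusted p under 0.05, 21 by DESeq2 and 0 by limma voom. Knockout females had 0 genes on both sets, with 615 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma voom over 24 libraries, and 1392, 1 and 0 over 23. The clock list was lower there in 13 of 15 genes over 23 libraries (camera adjusted p = 3.52e-07, adjusted p = 0.0175 with an estimated correlation, fry 0.0134). Wild-type males had 0, with 1114, 0 and 0 over 24 libraries and 3083, 170 and 0 over 23, and 44 without wild-type male paclitaxel replicate 3. Wild-type females had 0, with 5383, 563 and 0 over 24 libraries and 3088, 242 and 0 over 23. There Fcgrt lay at 16.3 CPM (n = 2) against 22.8 CPM (n = 3), with an edgeR adjusted p of 0.184, and leaving out either sound paclitaxel replicate from the 24 libraries gave 3835 (replicate 2) or 3408 (replicate 1) genes.

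The paclitaxel responses of separate sets of cords correlated across genes no more than permuted labels did. Over 24 libraries the log2 fold changes of wild-type and knockout correlated at Pearson's r of 0.0382 (Spearman's rho 0.0427) across 24725 genes, within the range of -0.0975 to 0.0911 of 100 draws with permuted labels. Females and males correlated at -0.0069 in wild-type, -0.0422 in knockout and 0.0054 over both genotypes (rho 0, -0.0242 and -0.0302). Over 23 libraries the 4 values of r were 0.0151, -0.0546, -0.0119 and -0.0337 (rho 0.0247, -0.0889, -0.0195 and -0.1226), all inside the ranges of their draws. The values of rho lay inside the ranges of their own draws too, as did r over genes with a mean of at least 1 CPM. There females and males over both genotypes had -0.241 over 23 libraries, within -0.393 to 0.440, and 11 of 100 draws lay as far from 0. These values are across genes, which are not independent replicates.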

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

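All values over 23 libraries, and the tests of a ganglion in place of cord, of the numbering of the libraries, of muscle, of GC content and length, of the time of day and of all lists in each split, were chosen only after the results were seen, while the counts of other splits of the samples were fixed in advance.

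Wild-type female paclitaxel replicate 3 stood apart from the other 23 libraries. A dorsal root ganglion collected in place of the cord may be the source, since the ganglion list lay 8.52 log2 units above the other libraries at the median while its astrocyte and myelin lists lay far below theirs. A full share of cord with ganglion added is argued against by the astrocyte list at 7.88% of the others. A response of wild-type females to paclitaxel is argued against too, because the other 2 libraries of the group had a summed ganglion list at a log2 ratio of at most -0.22 to the median of the 23. A swap of labels at some step before counting was not tested and stays open.

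The edgeR interaction of sex and treatment called 1259 genes over 23 libraries, and the library numbers 1 to 12 held exactly the female vehicle and male paclitaxel cords, 13 to 24 the others. A difference between these runs of numbers cannot be told apart from the interaction, because the design confounds them; the share of odd counts among genes with 1 to 20 counts, which depth and the choice of low genes can also move, was 36.4% ± 0.599 (SD, n = 12) in the first and 35.8% ± 0.739 (n = 11) in the second (permutation test, two-sided, p = 0.0423). With the muscle list as a covariate 361 genes passed, 308 of them among the 1259, so most of the calls were lost. The median size of the 1259 differences went from 0.275 to 0.285 and their median SE from 0.0695 to 0.0823. That the differences did not shrink speaks only weakly against carried-over skeletal muscle as the whole cause, since these genes were picked for large differences in the same data. A part played by muscle is not excluded. A bias by GC content or length is argued against as the whole cause but not as a part of it, since 703 genes passed with both trends removed, 494 of them among the 1259, with the median size down to 0.219 (SE 0.0622). A difference between the sexes stays open beside the numbering.

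Clock genes were lower with paclitaxel over 23 libraries in 12 of 15, with Arntl and Npas2 among the 3 higher ones. The numbering of the libraries is argued against as the whole cause, since it opposes the treatment in 1 sex. The list's median was negative in females (-0.15, 12 of 15 lower) and in males (-0.08, 10 of 15 lower), and 9 genes were lower in both. These medians carry no spread, so a part played by the numbering is not excluded. A different time of day at tissue collection could give the same picture, and so could a shift of the clock by the drug. For a single shift of phase, 11 members were looked at, with 2 (Arntl and Npas2) to be higher and 9 lower, and all 11 moved so. They were picked after the results were seen, and members such as Clock, Cry1 and Cry2 were left out, so this count decides nothing. The time of day and the drug cannot be told apart without the times of collection.

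For the clock list, moving the treatment labels within genotype and sex gave a -log10 camera p of at most 5.91 in the other splits against 10.1 for the real labels over 23 libraries, and 7.05 against 9.30 over 24. So 1 of 100 splits was as large in both cases, and chance is made unlikely for this list taken alone. It was singled out among 43 lists, however, and some list was as large in 59 of 100 splits over 23 libraries (highest other 29.3) and in 86 over 24 (highest other 19.66), so chance cannot be excluded for the largest of the lists with the preset correlation. With an estimated correlation over 23 libraries, the real value was 3.90, the highest of any list in the other splits 3.65 and 1 of 100 splits as large. Over 24 libraries 55 of 100 were as large (1.61, highest other 3.78). The margin over 23 libraries is small, that set was chosen after the results were seen, and the splits cover only 1 of the contrasts. Chance is therefore made less likely there but is not excluded. In 9 of the other splits over 23 libraries and 3 over 24, at least 1 list passed with an estimated correlation, so holding in this way is not by itself beyond chance. The value over 24 libraries also holds the ganglion-like library, which had 14 of 15 clock genes below the other libraries.

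For single genes in the paclitaxel contrasts over 24 libraries, the real counts were 0 in wild-type, knockout, all animals, the interaction of genotype and treatment, that of sex and treatment and that of all 3 factors. A real count of 0 makes all 100 splits as large by construction, so they say nothing on chance; the highest other counts were 1, 0, 0, 1, 0 and 0. Over 23 libraries the counts were 6 in knockout (1 of 100 splits as large, highest other 1) and 1259 for sex and treatment (1 of 100, highest other 810). Chance is made unlikely for both, but it is not excluded on a set of libraries chosen after the results were seen. Leaving out 1 further library removed all 6 calls in knockout. In all animals the count was 5 (3 of 100). The highest other counts there were 622 and 294, so chance is not excluded for these 5 genes, though the share lies under 0.05. The split with 622 genes may reflect a structure of the samples. It set 17 of the 23 libraries apart as their numbers 1 to 12 and 13 to 24 do, with a muscle difference that 19 splits reached. No split drawn did so for more (median 13), but 2 did so for as many, this one included, and the other called at most 294 genes. The split with 810 genes followed the numbers for 18 of 23, which again 2 splits reached and none passed. The other of these called at most 2 genes, so following the numbers does not by itself give a large count. For sex and treatment, following the numbers and following the real labels are the same thing. In wild-type the count was 0 (100 of 100, highest other 13), for genotype and treatment 0 (100 of 100, highest other 1) and for all 3 factors 0 (100 of 100, highest other 1), which again says nothing on chance.

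Moving the genotype labels, chance is made unlikely for knockout against wild-type under vehicle and over all animals. Under vehicle the counts were 1 gene over 24 libraries (1 of 100 splits as large, highest other 0) and 2 over 23 (1 of 100, highest other 0). Over all animals they were 2 genes over 24 (1 of 100, highest other 0) and 3 over 23 (1 of 100, highest other 1). Chance is not made unlikely over 23 libraries under paclitaxel, with 1 gene (6 of 100, highest other 7), nor for sex and genotype, with 1 gene (5 of 100, highest other 12). What the splits that called several times the real count follow was not examined. Over 24 libraries both had 0 genes (100 of 100, highest other 0), which says nothing on chance. Moving the sex labels, the count for males against females was 28 genes over 24 libraries (1 of 100, highest other 0) and 233 over 23 (1 of 100, highest other 11). These counts include genes of the sex chromosomes, which follow the labels by nature. Genes elsewhere were not counted apart, so the splits give no separate answer for them.

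Within a single combination of genotype and sex, 3 cords against 3 make 10 splits, too few for a share under 0.05, and treatment coincides with the numbering of the libraries. Over 24 libraries the real and highest other counts were 0 and 0 in wild-type females, 0 and 1 in wild-type males, 0 and 0 in knockout females and 0 and 0 in knockout males, and 10 of 10 splits were as large in each. Over 23 libraries they were 0 and 2 in wild-type males (10 of 10), 0 and 0 in knockout females (10 of 10) and 199 and 0 in knockout males (1 of 10).

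Other results stood out because a test of the difference between 2 effects passed. For sex and treatment over 23 libraries the genes with the smallest p had differences in log2 fold change of 0.60 (Fcgrt), 0.42 (Coq8a), 0.43 (Efhd1), 0.49 (Chst8) and 0.38 (Snrpa). Sex and genotype had 1 gene over 23 libraries, Ddx3y at -4.02, from near-zero counts in females. Lists past the threshold with the preset correlation numbered 13 over 24 libraries and 17 over 23 for genotype and treatment, 11 and 13 for sex and treatment, 14 and 16 for sex and genotype, and 16 and 15 for all 3 factors, and none of these held with an estimated correlation.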

How the results depend on the processing

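The alternatives fixed in advance were run on 24 libraries; the same alternatives on 23 libraries, the muscle covariate, the removal of GC and length trends and the left-out libraries for named genes were chosen only after the data were seen. Numbers are genes called, and where no reason is given the cause was not tested. Named genes kept direction in every setting run, each in the contrasts it was named for and Chrna7 apart. Of their values under the other settings, 249 stayed on their side of the threshold over 24 libraries, 21 newly passed and 9 no longer did, and over 23 libraries these numbers were 802, 57 and 20. With 1 library left out they were 878, 14 and 68 over 24 libraries and 2557, 18 and 369 over 23. For knockout against wild-type over all animals, the only contrast in which Chrna7 was followed through the settings, its direction and its side of the threshold held under all of them. Its response to paclitaxel in wild-type cords had a log2 fold change of 0.30 over 24 libraries and -0.13 over 23, called on neither set. With DESeq2 size factors in place of TMM every count stayed within 1.5 times. Depth was not varied on its own. In simulated counts of the 23 libraries, 95.5% of genes changed 1.5-fold were recovered for paclitaxel over all animals (24790 genes). With the ganglion-like library added it was 59.7% (24467 genes), so a count of 0 over 24 libraries leaves many changes of this size unseen. Of all genes called for this contrast, 19 of 200 were false over 23 libraries (38 of 222 by the DESeq2 Wald test) and 3 of 131 over 24. Some calls over 23 libraries may therefore be false. The simulated counts were drawn independently around 1 mean per gene, so they hold no structure by numbering, muscle or GC content. With the real 23 libraries, permuted labels called up to 622 genes for this contrast. The simulated shares may therefore be too favourable. For wild-type males, 3 against 3, the recovered shares were 77.6% (24766 genes) over 23 libraries and 40.3% (24433 genes) over 24. The replicate numbers gave no clear sign of pairing: 77 pairs of libraries with the same number correlated at 0.003 at the mean, and 154 other pairs at -0.0015. For 11 of the 23 libraries, however, the closest library of another group had the same number, so pairing is not excluded. The replicate block is given as a plain alternative.

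Over 24 libraries, the DESeq2 Wald test called 1 gene for paclitaxel in wild-type, 1 in knockout and 1 over all animals, 2 for genotype and treatment, 2 for knockout against wild-type under vehicle and 2 under paclitaxel, 101 for males against females, 394 for sex and treatment, 3 for sex and genotype, 563 in wild-type females and 21 in knockout males. With 1 surrogate variable the counts were 6 for paclitaxel in knockout, 5 over all animals, 1 for knockout against wild-type under paclitaxel, 228 for males against females, 1549 for sex and treatment, 1 for sex and genotype and 284 in knockout males. Limma voom and the replicate block both called 0 for knockout against wild-type under vehicle, the libraries of the compared groups alone gave 1 for paclitaxel in knockout, and genes with a mean of at least 1 CPM gave 1 for sex and treatment and 1 in knockout males. That filter moved the correlations of females and males to -0.0541 in wild-type, -0.1015 in knockout and -0.054 over both. Of 191 list calls over the 15 contrasts, 1 held with an estimated correlation and 1 with fry.

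Over 23 libraries, testing without a filter, where genes with reads in few libraries enter, called 254 for paclitaxel in wild-type, 470 in knockout and 338 over all animals, 366 for genotype and treatment, 111 for knockout against wild-type under vehicle, 215 under paclitaxel and 99 over all animals, 749 for males against females, 2181 for sex and treatment, 813 for sex and genotype, 199 for all 3 factors, 663 in wild-type females, 631 in wild-type males, 268 in knockout females and 1198 in knockout males. The DESeq2 Wald test called 4 for paclitaxel in wild-type, 183 in knockout and 242 over all animals, 3 for knockout against wild-type under paclitaxel and 5 over all animals, 625 for males against females, 2520 for sex and treatment, 250 for sex and genotype, 242 in wild-type females, 170 in wild-type males, 1 in knockout females and 1334 in knockout males. The replicate block gave 0 for knockout against wild-type under paclitaxel, 9 for paclitaxel over all animals, 1891 for sex and treatment, 83 in wild-type females and 455 in knockout males. With 1 surrogate variable these were 0 for knockout against wild-type under paclitaxel, 2021 for sex and treatment and 606 in knockout males. The libraries of the compared groups alone gave 1 for paclitaxel in knockout, 1 for knockout against wild-type under vehicle and 0 under paclitaxel. Limma voom gave 0 for sex and genotype, and genes with a mean of at least 1 CPM gave 534 in knockout males. For sex and treatment, the muscle covariate gave 361 and the removal of GC and length trends 703. Genes with a mean of at least 1 CPM moved the correlations to 0.052 for wild-type and knockout, and for females and males to -0.1613 in wild-type, -0.0875 in knockout and -0.2414 over both. Of 199 list calls, 5 held with an estimated correlation and 5 with fry.

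With each of the 24 libraries left out, the lowest and highest counts were 0 and 6 for paclitaxel in knockout, 0 and 5 over all animals, 0 and 2 for knockout against wild-type under vehicle, 0 and 1 under paclitaxel, 16 and 233 for males against females, 0 and 1259 for sex and treatment, 0 and 1 for sex and genotype, 0 and 3835 in wild-type females, 0 and 1 in knockout females and 0 and 199 in knockout males. The correlations ran from -0.0026 to 0.0619 for wild-type and knockout, and for females and males from -0.0547 to 0.0263 in wild-type, -0.027 to 0.0029 in knockout and -0.0337 to 0.0362 over both. All values in knockout lay above the -0.0422 of the 24 libraries because a smallest group of 2 lets the filter admit 25372 to 25521 genes in place of 24725; over the shared genes alone they ran from -0.053 to -0.0173, a check added after seeing the data. The adjusted p of the sex chromosome list for males against females ran from 0 to 0.00255, and its direction was reversed without wild-type female paclitaxel replicate 3.

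With each of the 23 libraries left out, the counts were 0 and 4 for paclitaxel in wild-type, 0 and 332 in knockout, 2 and 62 over all animals, 0 and 1 for genotype and treatment, 1 and 3 for knockout against wild-type under vehicle, 0 and 2 under paclitaxel and 3 and 5 over all animals, 65 and 324 for males against females, 248 and 2419 for sex and treatment, 1 and 51 for sex and genotype, 0 and 1 for all 3 factors, 0 and 2 in wild-type females, 0 and 44 in wild-type males, 0 and 1 in knockout females and 0 and 1591 in knockout males. The correlations ran from -0.0136 to 0.0317 for wild-type and knockout, and for females and males from -0.0789 to -0.0198 in wild-type and -0.058 to -0.0017 over both. The adjusted p of the interferon list for knockout against wild-type ran from 1.63e-15 to 0.9996, with the direction reversed without wild-type male vehicle replicate 1.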

Other observations

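All values over 23 libraries, the tests below on the lysozyme genes and on the segment of the X chromosome, and the choice of the segment's genes, were made only after the values were seen.

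Beyond the comparisons above, several lists leaned to 1 side in the sex interaction over 23 libraries without holding with an estimated correlation. Antigen presentation and complement genes had more positive responses in males in 18 of 20 (adjusted p = 0.459 with an estimated correlation), with Cd74, the invariant chain of class II antigen presentation, at a difference of 1.41 (edgeR adjusted p = 0.0288), a call lost without any 1 of 6 libraries, such as wild-type female paclitaxel replicate 1 (0.0931). Cholesterol synthesis genes followed in 15 of 18 (adjusted p = 0.528 with an estimated correlation), with 11 passing when adjusted over the list alone, 10 of them positive, and with Fdft1, squalene synthase, at 0.32 and Srebf2, the master regulator of the pathway, at 0.26 (edgeR adjusted p = 0.0164 and 0.0169). Among astrocyte and myelin genes, Aldh1l1 was at 0.39 (edgeR adjusted p = 0.0244), a call lost without any 1 of 5 libraries such as wild-type female paclitaxel replicate 2 (0.0642), and Cnp, an enzyme of myelin, at 0.34 (edgeR adjusted p = 0.0153). All of this shares the confounding with the numbering of the libraries.

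In wild-type males over 23 libraries, 18 of 18 immediate early genes, which neurons transcribe upon activity, were higher with paclitaxel (adjusted p = 0.406 with an estimated correlation). In knockout males the stress-linked receptor gene Eda2r fell by 0.77 and Nr4a3, an immediate early gene, by 0.71 on the log2 scale (edgeR adjusted p = 0.0338 and 0.0340). Both calls were lost without knockout male paclitaxel replicate 2 or 3 or knockout male vehicle replicate 2 or 3, with an adjusted p of up to 0.263. In these males, too, treatment coincides with library numbers 1 to 12 and 13 to 24, from which neither result can be told apart.

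A first hypothesis concerns Lyz2 and Lyz1 in knockout cords. Fewer macrophages and monocytes are argued against, since the 13 other members of their list had a median log2 fold change of -0.0774 over 23 libraries against -1.06 for Lyz2. Reads of Lyz2 counted for its neighbour do not make up the loss, as the gain of Lyz1 was 5.1% of the fall of Lyz2 in CPM. A candidate explanation is a driver allele that interrupts 1 copy of Lyz2, because knockout cords held 47.2% of the wild-type level of Lyz2 in CPM without TMM factors. The sources used here do not name the driver of the knockout, so this cannot be told apart from regulation of Lyz2 by the loss of Chrna7.

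A further hypothesis is an extra copy of the far end of the X chromosome in most males. Of the 12 males, 9 had all or all but 1 of the 9 expressed genes from Tmsb4x to BC022960 (GRCm38, X chromosome, 167207093 to 169370003, 2.16 Mb) above every one of the 11 females, with median ratios of 1.69 to 2.08 to the female mean. Knockout male paclitaxel replicate 1 (0.959), wild-type male vehicle replicate 3 (1.01) and knockout male vehicle replicate 3 (1.07) did not. Depth, cell mix or RNA quality is argued against, since the median ratio of the 20 genes before the segment departed from 1 by at most 0.078 in a male, and the next genes on either side, Egfl6 and Mid1, had median ratios of 1.05 and 1.04. The levels could reflect a second copy carried on the Y chromosome, as in the Yaa translocation known from lupus-prone mice, which holds Tlr7, but neither the genomes nor the breeding of these males were available to a test here. The carriers are spread over both genotypes and treatments, and no comparison was made between them and the other males.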
